A study of Mus musculus with 83 samples.

How the data were processed

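The samples are 83 regions of femur sections from wild-type mice, 41 at 3 months and 42 at 18 months, each region drawn around a megakaryocyte chosen by CD41 staining, per the series description. Per the labels' protocols, sections were incubated with barcoded RNA probes carrying a photocleavable linker, each region was illuminated, and its barcodes were collected into a well of a plate and indexed with 18 cycles of PCR. The probes were those of the mouse whole transcriptome atlas, per the series description. The deposited single-region files hold deduplicated counts per probe, made per the file headers with the GeoMx NGS Pipeline 2.3.4, which trims, stitches and aligns the reads to the probe barcodes and removes duplicates by unique molecular identifiers. Probes with no count are left out of those files. The deposited expression table has 1234 rows. Compared with the single-region files, it holds counts with each 0 replaced by 1 and no normalization, so its unit is raw counts with a floor, as deposited. Of its rows, 1230 equal the counts of 1 probe, 3 the geometric mean of 2 probes, and 1 summarises the negative probes. The values look like a selection of probes with at least 3 counts in at least 5 regions, a rule read from the data that 1 probe outside the table also meets. All columns of the table were used.

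The plan written before the data were examined foresaw either normalized values or whole-number counts. The table held counts with a floor, so zeros were put back from the single-region files, and the edgeR test foreseen for counts was used. Zeros made up 44.3% of the values of the table genes. Gene names come from the table only. A probe has a name where its counts equal those of a table gene, which held for 394 of the 399 probes tested. The other 18939 probes of the files were not in the table and were used without names.

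The comparison of genes covered all 1233 genes of the table with no further filter. It used edgeR 4.0.16 with TMM factors over the table genes, a robust quasi-likelihood fit and a 2-sided test of 18 against 3 months, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The common biological coefficient of variation was 0.380. The comparison of probes used the same test on the 399 probes with a mean of at least 1 count, with TMM factors over those probes, and had a coefficient of 0.317. Fold changes are on the log2 scale, 18 over 3 months. The SE beside an edgeR fold change is the size of that fold change divided by the square root of its F statistic. Abundances are counts per 10000 counts of all probes of a region, a scaling that differs from the TMM scaling of the fold changes. Lists were tested with camera on the gene test, with a preset correlation of 0.01, where at least 5 members were measured. Of 26 lists, 24 were fixed as gene names before the data were examined and the ribosomal protein and oxidative phosphorylation genes by symbol pattern. In all, 23 had a measured gene and 11 had at least 5.

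Region measures were compared with permutation tests of 100000 resamples, and correlations with permutation p of the same number. The mean of a list in a region is the mean of the log2 deposited values. Whether the age difference of the identity list differed between lower-numbered and higher-numbered regions was tested by permuting the residuals of the model without the interaction, chosen after seeing the data. Spread is the median over genes of the SD of log2 deposited values, set against 100 splits of the regions. Both correlations were repeated without the 2 regions farthest from the median of the identity list, or of the total count where that was the other variable. Alternatives fixed before the data were examined covered pseudocounts of 0.5 and 5, other scalings, a Wilcoxon test, DESeq2 1.42.0, limma 3.58.1 with voom, stricter and looser filters, depth as a covariate, counts thinned to 5000 per region, and subsets of regions. One such subset left out the 4 regions with fewer than 0.5 times the median total count, all at 3 months, and others kept the lower-numbered or the higher-numbered regions of each age (21 and 20 at 3 months, 21 and 21 at 18 months). Further alternatives were chosen after seeing the data: the table as deposited, limma and DESeq2 on genes, all probes as library size, TMMwsp on genes, removal of counts high in 1 region, leaving out each region, leaving out plate row A, counts summed per plate row, and camera on the lower-numbered or the higher-numbered regions. The plate row is the row of the well given with each file.

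The text names genes by a rule fixed before the data were examined. For the age comparison these are the 12 called genes with the largest log2 fold change each way whose direction is the same in the lower-numbered and higher-numbered regions, then up to 4 called members of each list. For the description they are the 15 most abundant genes and the 8 most abundant identity genes. Of called probes without a name, at most 2 each way are given by identifier. Further identifiers are given only for the test of neighbouring identifiers, which was chosen after the result was seen. Named beyond the rule after their values were seen were members of lists with few measured genes and the genes of the plate-row test. So were the genes with a high count in a single region and the probes of Actg1, Smc3, Nrgn and Rnaset2a. The list members Tubb1, Actg1, Myl9, Clu, Srgn and Gapdh were also named beyond it.

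The pipeline was tested on simulated counts with the depths of these regions, in which 200 genes changed. The edgeR gene test recovered 4 of 67 genes changed 1.5-fold, 26 of 67 changed 2-fold and 56 of 66 changed 3-fold, with 4 false calls of 90, so a 1.5-fold change is mostly missed at this depth. The edgeR probe test recovered 24 of 67, 57 of 67 and 65 of 66, with 1 false call of 147. With no change simulated, edgeR gave 3 calls among genes and 0 among probes. The list test called the list that was shifted 1.5-fold and 1 other list, and 0 with no shift. The permutation test gave p under 0.05 in 9 of 100 runs with no difference and 100 of 100 with a difference of 1 SD. The correlation test did so in 6 of 100 runs at a correlation of 0 and in 98 of 100 at 0.5.

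All regions were sequenced on 1 flow cell, per the file headers, and plate rows A to D hold only 3-month regions and rows E to H only 18-month ones. Age, plate row and whatever goes with them, such as slide or animal, cannot be told apart. No region's counts repeated another's: the closest pair at each age differed in 7185 probes at 3 months and 8698 at 18 months. Analyses used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with seed 11. GENCODE M21 was used for the GC content of transcripts only. No coordinates are given, since the files name no genome build or positions.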

Results

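The series measured the transcripts of megakaryocytes, the large bone marrow cells that release platelets, inside sections of the mouse femur. Each region was drawn around a megakaryocyte picked out by immunofluorescence for CD41, a platelet integrin chain encoded by Itga2b. The assay was GeoMx digital spatial profiling, in which barcoded probes bind transcripts in the section, ultraviolet light releases the barcodes of a chosen region, and the barcodes are counted by sequencing. There were 83 regions, 41 from mice aged 3 months and 42 from mice aged 18 months, all wild type. The deposited counts covered 20175 probes and summed to 876025. A region held 9562 ± 3696 counts at 3 months (SD, n = 41, range 3537 to 17370) and 11524 ± 5987 at 18 months (SD, n = 42, range 4856 to 29527). At this depth the median probe had a mean of 0.446 counts per region. The deposited expression table named 1233 genes, which held 21.8% of all counts. The mean of its negative-probe row was 1.02 ± 0.03 (SD, n = 83). Since 1 was the lowest value the table could hold, that row cannot show how far background lay below 1. The labels do not tie regions to animals. Some regions of each age therefore share an animal wherever there were fewer mice than regions.

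**Figure D1:**
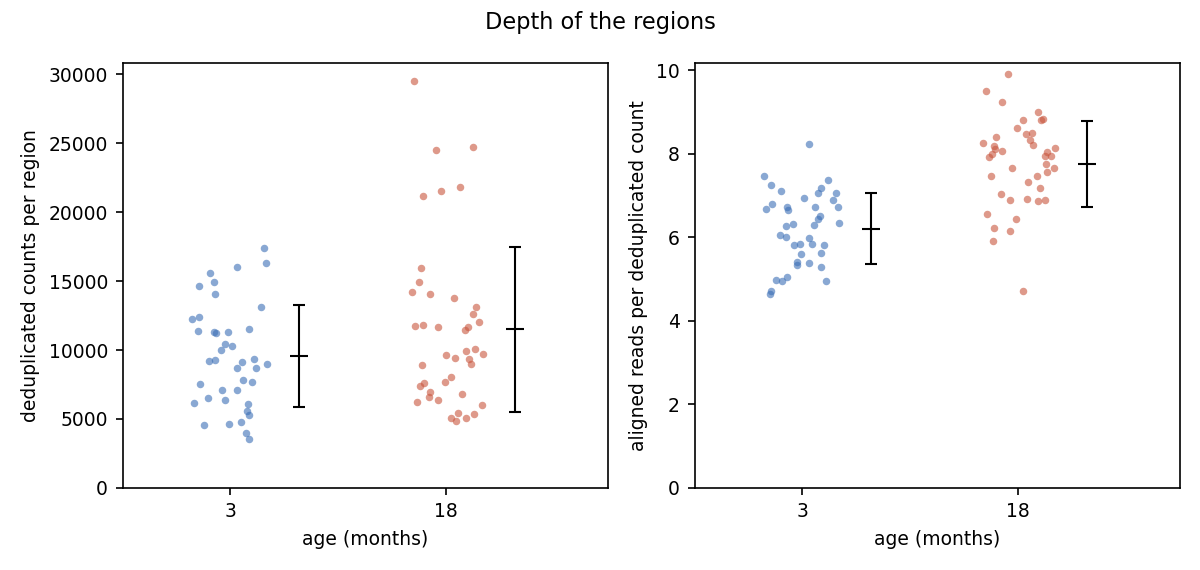
The left plot gives the deduplicated counts of each region and the right plot the aligned reads per deduplicated count, by age in months. Each point is a region, and the bars show the mean and SD of 41 regions at 3 months and 42 at 18 months, with means of 9562 and 11524 counts and of 6.21 and 7.76 reads per count.

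The highest counts of named genes in these regions were mostly those of predicted genes, and the counts of megakaryocyte genes lay below them. Over all regions LOC118568634 came first with 184 ± 33.9 counts per 10000 counts (SD, n = 83), followed by Gm52800 with 134 ± 27.5, Gm10265 with 124 ± 88.4, Chic2 with 81.1 ± 18.4 and LOC118568632 with 50.5 ± 11.7. The order differed between the ages, since Gm10265 was the first at 18 months (186, against 173 for LOC118568634) and the fourth at 3 months (60.9, below Chic2 at 88.5). Gm52523, Gm52436, Gm10406, Gm21783, Lrr1, LOC118568783, Gm3248, Gm51591, Gm6958 and Gm36327 followed, from 47.7 down to 10.9 counts per 10000. These 15 genes held 7.80 ± 1.15% of all counts (SD, n = 83). Pf4, the chemokine platelet factor 4 of the alpha granules, was the most abundant gene of the megakaryocyte and platelet identity list, at rank 35 of 1233 with 6.08 ± 4.69 counts per 10000. Ppbp, the precursor of another alpha-granule chemokine, ranked 80 with 2.99 ± 3.525. Itga2b ranked 131 with 1.92 ± 1.81, and the platelet tetraspanin Cd9 ranked 203 with 1.43 ± 1.70. Treml1, a receptor stored in alpha granules, ranked 281 with 1.13 ± 1.28 and Rasgrp2, an exchange factor that activates Rap1 in platelets, ranked 301 with 1.08 ± 1.14. Itgb3, the integrin chain that pairs with CD41, ranked 362 with 0.990 ± 1.09, and Alox12, the platelet lipoxygenase, ranked 445 with 0.894 ± 1.08. These ranks pool the ages, and the order differed between them: at 18 months Itga2b (1.30) lay above Ppbp (1.25) and Rasgrp2 (1.16) above Cd9 (0.820), against 2.56, 4.77, 1.00 and 2.06 at 3 months. The 64 measured ribosomal protein genes held 1.29 ± 0.21% of the counts. The haemoglobin gene Hbb-b2 ranked 40 with 5.54 ± 4.68 counts per 10000. Its count lay below that of Pf4 at 3 months (5.43 against 7.92) and above it at 18 months (5.64 against 4.28). Many of the predicted genes belong to families of near-identical copies, so a probe's count for them may not come from a sole locus. Probes may also differ in how well they bind, which was not measured. The ranks and comparisons between genes given here are therefore of counts, not of transcript numbers.

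The first comparison asked which transcripts of the megakaryocyte regions differ between 3 and 18 months. The genes with lower transcript counts at 18 months were Ppbp, Tmsb4x, Actb, Pf4, Cd9, Tubb4b and Ppif. Ppbp fell by 1.71 ± 0.23 on the log2 scale (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.53e-11), from 4.77 ± 4.18 to 1.25 ± 1.23 counts per 10000 (SD, n = 41 and 42). Tmsb4x, whose product thymosin beta 4 binds actin monomers, fell by 1.51 ± 0.20 (SE; edgeR adjusted p = 2.05e-11), from 6.46 ± 3.94 to 1.98 ± 1.65. Actb, which encodes beta-actin, fell by 0.86 ± 0.18 (SE; edgeR adjusted p = 0.000118), from 7.77 ± 3.35 to 3.93 ± 1.82. Pf4 fell by 0.77 ± 0.17 (SE; edgeR adjusted p = 0.00108), from 7.92 ± 5.11 to 4.28 ± 3.44. Ppbp lay below the 3-month median in 38 of the 42 regions at 18 months, Tmsb4x in 40, Actb in 42 and Pf4 in 33. Cd9 fell by 1.20 ± 0.29, Tubb4b, a beta-tubulin isotype, by 1.32 ± 0.36, and Ppif, which encodes the mitochondrial cyclophilin D, by 1.03 ± 0.29 on the log2 scale (SE), with edgeR adjusted p of 0.00313, 0.0251 and 0.0368. These 3 had low counts, Cd9 2.06 and 0.820 per 10000 at 3 and 18 months, Tubb4b 1.00 and 0.378, and Ppif 1.79 and 0.819. Background was estimated at 0.422 counts per 10000. Tubb4b had a count in 11 of the 42 older regions and at most 4 counts in any region.

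The transcripts that rose were those of 2 abundant predicted genes and 5 others. Gm10265 rose by 1.85 ± 0.16 on the log2 scale (SE; edgeR adjusted p = 4.76e-16), from 60.9 ± 15.3 to 186 ± 86.4 counts per 10000 (SD, n = 41 and 42). Gm52523 rose by 1.10 ± 0.12 (SE; edgeR adjusted p = 6.59e-17), from 32.9 ± 11.9 to 62.2 ± 25.5. Marcks, a substrate of protein kinase C that links actin to the membrane, rose by 1.28 ± 0.17 (SE; edgeR adjusted p = 2.13e-11), from 3.96 ± 2.45 to 8.57 ± 3.38. Sprn, which encodes the prion-like protein Shadoo, rose by 1.85 ± 0.24, and Tysnd1, a protease of peroxisomes, by 1.72 ± 0.24 (SE). Their edgeR adjusted p were 2.75e-12 and 1.18e-10. The uncharacterised gene 1110065P20Rik rose by 1.12 ± 0.19 and Cd99, a surface glycoprotein of leukocytes, by 1.02 ± 0.17 (SE), with edgeR adjusted p of 2.77e-07 and 2.76e-07. Gm10265 lay above the 3-month median in 41 of the 42 regions at 18 months, though regions 88 to 91 of row H held 51.3 to 81.7 counts per 10000 and the other 6 regions of that row 163 to 308. Marcks lay above it in 40, Gm52523 in 39, Sprn and Tysnd1 in 36, and 1110065P20Rik and Cd99 in 35. Together these 7 genes held 1.08 ± 0.25% of the counts of a region at 3 months and 2.78 ± 1.17% at 18 months (SD).

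In all, 14 of the 1233 genes passed the threshold, 7 that rose and 7 that fell, and 103 had an unadjusted p under 0.05 in the same edgeR test. The median log2 fold change of all genes was 0.11 with the TMM scaling and -0.065 when each region was scaled to the same total, and that scaling gave 20 genes, 7 that rose and 13 that fell. TMM factors were high in shallow regions, such as 2.32 in region 17 with 557 counts of table genes. They were low in deep ones, such as 0.631 in region 86 with 6753. The sign of a fold change near 0 therefore depends on the scaling. The labels do not say which regions share an animal, and where some do, the p-values of this test over regions are too small. With the higher-numbered regions of each age alone, Ppbp stood at -0.68 (edgeR adjusted p = 0.762), Cd9 at -0.80 (0.667), Ppif at -0.25 (0.955) and Pf4 at 0.051 (0.988), and with the lower-numbered ones Tysnd1 stood at 1.24 (0.0663), Cd99 at 0.65 (0.412) and Actb at -0.79 (0.101). Tubb4b passed in neither set, at -1.46 (edgeR adjusted p = 0.342) in the lower-numbered and -1.28 (0.496) in the higher-numbered regions. Ppif left the threshold in 21 of the 83 fits that left out 1 region each, with an adjusted p of up to 0.102. Across the alternatives Tubb4b did not pass in 9 of 16, Ppif in 7 of 18 and Cd9 in 3 of 18, and Pf4 was weaker in 7 of 18 and turned in 1. With the Wilcoxon test the adjusted p of Tubb4b, Cd9, Ppif and Pf4 were 0.144, 0.156, 0.479 and 0.171. Tubb4b also left the threshold without region 5, 31 or 35 of the 3-month group, with edgeR adjusted p of 0.0601, 0.0609 and 0.0514 and log2 fold changes of -1.24, -1.25 and -1.27.

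**Figure D2:**
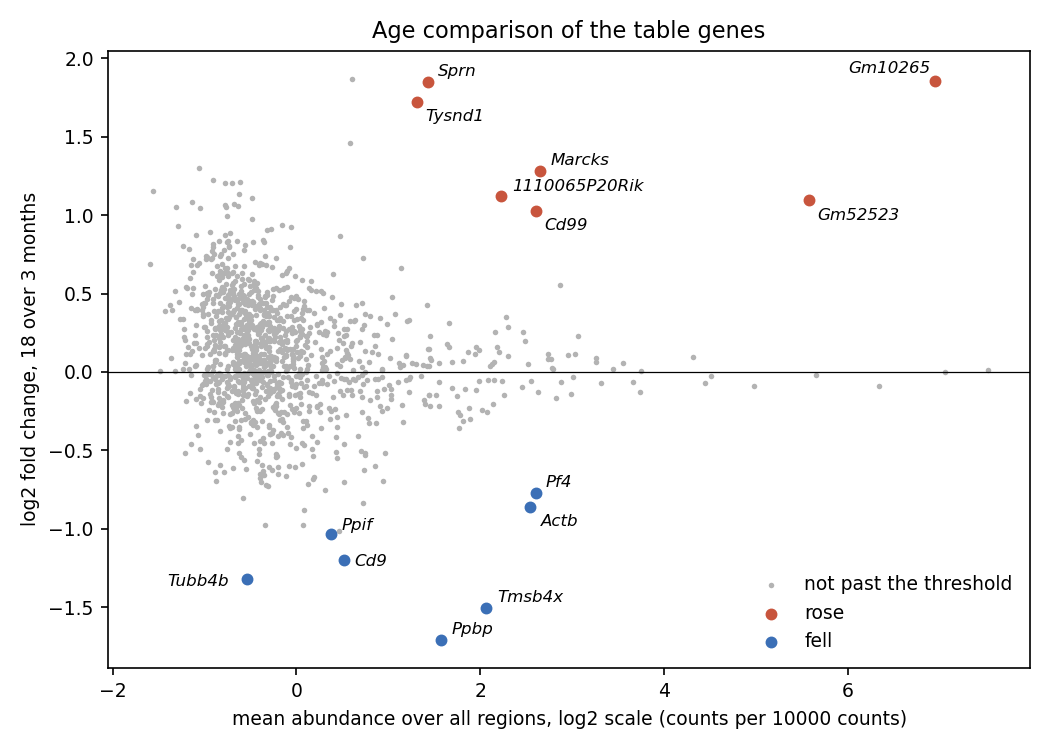
The vertical axis gives the log2 fold change of each of 1233 genes, 18 over 3 months, and the horizontal axis its mean abundance in counts per 10000 counts on a log2 scale. Coloured points are the 7 genes that rose and the 7 that fell, among them Gm10265 at 1.85 and Ppbp at -1.71.

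Ppbp, Pf4 and Tmsb4x were not spread evenly over the regions of the younger mice. The regions lay in 8 rows of a collection plate, rows A to D with the 3-month regions and E to H with the 18-month ones, so no row held both ages. Ppbp stood at 10.4 ± 4.35 counts per 10000 in row A (SD, n = 9), 4.13 ± 2.97 in row B (n = 11), 2.97 ± 2.16 in row C (n = 12) and 2.37 ± 2.03 in row D (n = 9). In rows E to H it stood at 1.22, 0.627, 1.54 and 1.57. Pf4 stood at 12.8, 9.65, 5.74 and 3.82 counts per 10000 in rows A to D and at 4.33, 2.88, 3.86 and 6.08 in rows E to H. Tmsb4x stood at 10.9, 5.70, 6.09 and 3.48 and then at 2.00, 1.70, 1.64 and 2.60. Actb stood at 9.21, 6.34, 7.92 and 7.90 and then at 4.26, 3.83, 3.33 and 4.34. The row means of Ppbp, Tmsb4x and Actb, but not of Pf4, were lower in each 18-month row than in any 3-month row. An edgeR quasi-likelihood test between the rows of the 3-month regions, chosen after seeing the data, called 5 of 1233 genes, Ppbp (adjusted p = 0.000103), Hbb-b2 (0.000103), Pf4 (0.00175), Lgals3 (0.0134) and Tmsb4x (0.0187). The other genes that fell did not pass it: Cd9 (adjusted p = 0.491), Tubb4b (0.716), Ppif (0.830) and Actb (0.973). The same edgeR test within the 18-month regions called 2, Hbb-b2 (adjusted p = 5.77e-06) and Rgs19 (2.33e-05), and 66 genes had an unadjusted p under 0.05. With the 9 regions of row A left out of the age comparison, also chosen after seeing the data, edgeR called 11 genes. Of the 7 genes that fell, Ppbp (-1.26, adjusted p = 0.00022), Tmsb4x (-1.27, 1.69e-06) and Actb (-0.86, 0.000525) then stayed past the threshold. Pf4 stood at -0.58, Cd9 at -0.97, Tubb4b at -1.18 and Ppif at -0.85 on the log2 scale, with edgeR adjusted p of 0.186, 0.186, 0.235 and 0.324. With counts summed per plate row, again chosen after seeing the data, Ppbp (-1.99, edgeR adjusted p = 0.297), Pf4 (-0.98, 0.488) and Gm52523 (1.05, 0.219) did not pass, while edgeR called 15 genes. Regions of a row may come from the same animal, which the labels do not give, and these p-values over regions are then too small.

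**Figure D3:**
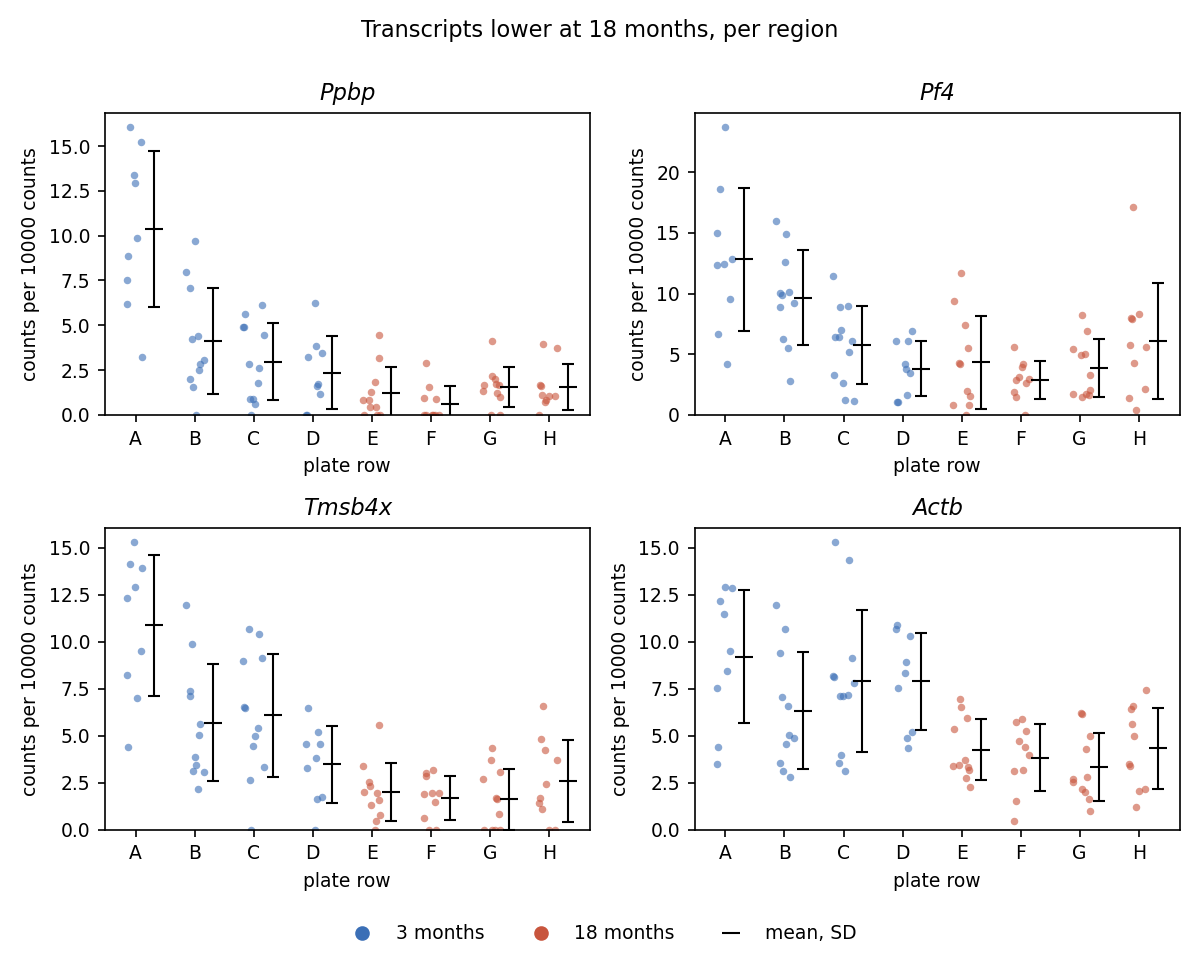
Counts per 10000 counts of Ppbp, Pf4, Tmsb4x and Actb in each region, by plate row, with the mean and SD of each row beside the points. Rows A to D hold the 41 regions at 3 months and rows E to H the 42 at 18 months, and Ppbp goes from a mean of 10.4 in row A to 2.37 in row D.

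**Figure D4:**
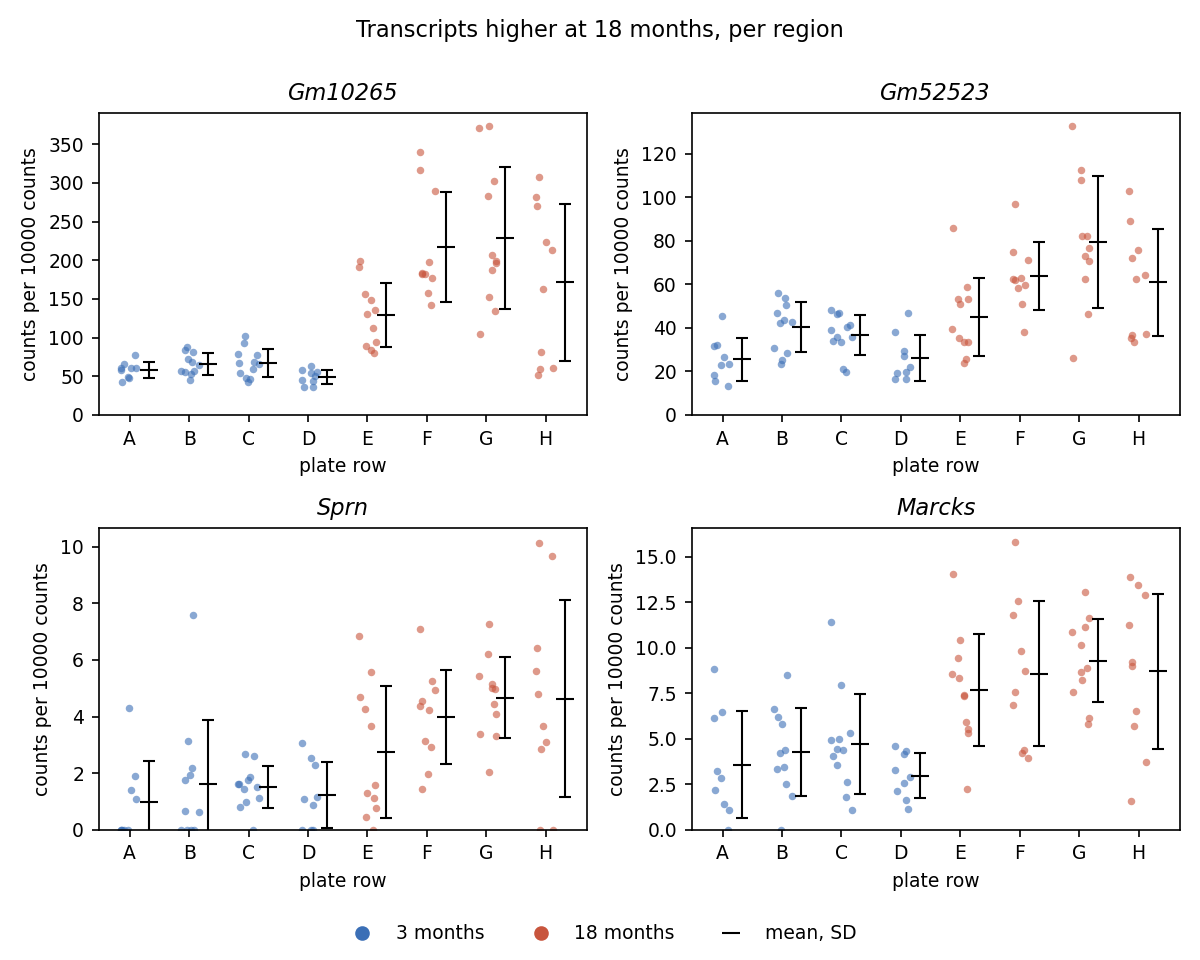
Counts per 10000 counts of Gm10265, Gm52523, Sprn and Marcks in each region, by plate row, with the mean and SD of each row beside the points. The row means of Gm10265 lie between 49.4 and 67.0 in rows A to D, at 3 months, and between 129 and 228 in rows E to H, at 18 months.

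The next comparison asked whether groups of genes fixed before the data were examined changed together with age. The list of megakaryocyte and platelet identity had 14 measured genes, of which 0 rose, 3 fell (Ppbp, Pf4 and Cd9) and 11 did not pass. Adjusted over the list alone, 4 genes passed, the fourth being Itga2b. Its median log2 fold change was -0.34, and camera, which sets a list against all other genes, called it lower at 18 months (Benjamini-Hochberg adjusted p = 4.51e-08, and adjusted p = 0.000858 with an estimated correlation). Its genes together made up 26.9 ± 13.5 counts per 10000 at 3 months and 15.1 ± 6.50 at 18 months (SD, n = 41 and 42). Of these counts Pf4 held 7.92 at 3 months and 4.28 at 18 months, and Ppbp 4.77 and 1.25. Itga2b stood at -0.70 ± 0.26 (SE; edgeR adjusted p = 0.184) and passed in 4 of 18 alternatives. CD41 staining chose the regions at both ages, and how far that choice bears on Itga2b transcripts was not tested. Treml1 stood at -0.69 ± 0.30 (edgeR adjusted p = 0.441), while Rasgrp2 at 0.23 ± 0.30 and Tubb1, the platelet beta-tubulin, at 0.14 ± 0.36 were the 2 members above 0, with edgeR adjusted p of 0.897 and 0.967. Scaled to all counts without the genes that rose, Rasgrp2 stood at 0.23 and Tubb1 at -0.035.

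The list of cytoskeleton and proplatelet formation had 13 measured genes, of which 0 rose, 2 fell (Tmsb4x and Actb) and 11 did not pass, and 3 passed when adjusted over the list alone. Its median log2 fold change was -0.26 and camera called it lower (adjusted p = 1.34e-08, and adjusted p = 0.000205 with an estimated correlation). Actg1, which encodes gamma-actin, stood at -0.83 ± 0.27 (SE; edgeR adjusted p = 0.0931) and Myl9, a myosin regulatory light chain, at -0.67 ± 0.30 (edgeR adjusted p = 0.494). The list of granule cargo and biogenesis had 8 measured genes, of which 0 rose, 2 fell (Ppbp and Pf4, both shared with the identity list) and 6 did not pass, and 2 passed when adjusted over the list alone. Its median log2 fold change was -0.45 and camera called it lower (adjusted p = 3.32e-07, and adjusted p = 0.000205 with an estimated correlation). Clu, which encodes the secreted chaperone clusterin, stood at -0.70 ± 0.33 (SE; edgeR adjusted p = 0.526) and Srgn, the proteoglycan core serglycin, at -0.24 ± 0.29 (edgeR adjusted p = 0.886). These 3 lists were the ones called of the 11 with at least 5 measured genes, and their genes overlapped. The identity and granule lists were not tested without Pf4 and Ppbp. The calls did not all hold in the higher-numbered regions alone, where camera, run there after seeing the data, gave adjusted p of 0.879 for the identity list, 0.845 for the granule list and 0.0347 for the cytoskeleton list. In the lower-numbered regions these were 5.40e-16, 1.89e-12 and 4.96e-10. Without plate row A, also chosen after seeing the data, they were 0.000557, 0.000189 and 0.000116.

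The other 8 tested lists were not called, and 0 of their genes passed over all genes or when adjusted over the list alone. The 64 ribosomal protein genes had a median log2 fold change of 0.08 (camera adjusted p = 0.911) and the 18 oxidative phosphorylation genes of 0.11 (0.911), both close to the median of all genes. Glycolysis, with 7 genes, had a median of 0.08 (camera adjusted p = 0.911), and its most abundant member Gapdh stood at 0.29 ± 0.18 (SE; edgeR adjusted p = 0.699). The medians were 0.06 for 8 proteasome and ubiquitin genes (camera adjusted p = 0.933), 0.08 for 5 cell cycle genes (0.933) and 0.10 for 5 autophagy and lysosome genes (0.933). They were -0.02 for 6 chaperone genes (0.911) and 0.04 for 5 genes known to rise in aged haematopoietic stem cells (0.911). For those lists with a median and a mean above 0, camera's direction was nevertheless lower, since it sets a list against the mean of all other genes. The test rests on the fit over regions whose animals the labels do not give, so where some share an animal its p-values are too small as well.

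Lists with fewer than 5 measured genes were described without a test. The interferon response had 3 genes, none past the threshold over all genes and 1 when adjusted over the list alone, Mx1, a dynamin-like antiviral protein, at 1.08 ± 0.39 on the log2 scale (SE; edgeR adjusted p = 0.175). Mx1 held 0.218 counts per 10000 at 3 months and 0.683 at 18 months, near a background estimated at 0.422, with a count in 28 of 83 regions. Trp53, which encodes p53, stood at 0.43 ± 0.38 and Sesn1, a sestrin induced by p53, at 0.55 ± 0.35 (SE; edgeR adjusted p = 0.811 and 0.719). Of 4 antigen presentation genes, the class I gene H2-Q6 stood at 0.25 ± 0.28 and the chaperone gene Calr at -0.62 ± 0.35 (SE; edgeR adjusted p = 0.885 and 0.667). The chemokine gene Ccl4 stood at 0.26 ± 0.33, Zfp36l1, an mRNA decay factor of the immediate early list, at -0.10 ± 0.32, and Mmp14, a membrane metalloproteinase of the matrix list, at -0.19 ± 0.37 (SE), with edgeR adjusted p of 0.886, 0.977 and 0.956. None of the genes fixed as megakaryocyte transcription factors was among the 1233.

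Markers of other marrow cells were measured by a few genes each and did not pass the age comparison. The erythroid genes Hbb-b2, Hba-a1 and Hbb-b1 stood at 0.25 ± 0.26, -0.33 ± 0.25 and 0.08 ± 0.31 on the log2 scale (SE; edgeR adjusted p = 0.861, 0.768 and 0.979). Hbb-b1 and Hbb-b2 are close paralogs whose probes may share transcripts. Hbb-b2 differed between plate rows of the same age, from 1.56 ± 1.82 counts per 10000 in row D to 8.61 ± 7.68 in row B and from 1.32 ± 1.71 in row E to 8.02 ± 3.23 in row F (SD, n = 9, 11, 11 and 10). Padi4, a neutrophil deiminase, stood at -0.02 ± 0.27, the macrophage genes Mrc1 and Lgals3 at 0.11 ± 0.37 and -0.64 ± 0.37, and the adaptor Lat, of the T and NK cell list, at -0.45 ± 0.31 (SE), with edgeR adjusted p of 0.991, 0.977, 0.669 and 0.751. Padi4 held 0.448 and 0.455 counts per 10000 at 3 and 18 months, Mrc1 0.524 and 0.461, and Lgals3 0.701 and 0.382. The background was estimated at 0.422, so these 3 genes say little about the cells they mark. Whether Lat counts came from T cells or from the megakaryocyte was not tested. Runx2, the osteoblast transcription factor, stood at 0.81 ± 0.37 (SE; edgeR adjusted p = 0.498), and it passed when adjusted over the list alone, a list with 1 measured gene. It held 0.464 and 0.884 counts per 10000 at 3 and 18 months, the first of them close to background. Vpreb1, a surrogate light chain of B cell precursors, stood at 1.46 ± 0.49 (SE; edgeR adjusted p = 0.162) and likewise passed when adjusted over its list of 1 gene. Region 71, at 18 months, held 63 of its counts, and no other region held more than 4. No stromal, endothelial, adipocyte or progenitor marker of the fixed lists was among the 1233 genes. Regions may share an animal here too, which makes p-values over regions too small.

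The same comparison was made on the counts of single probes, whatever gene they belong to. Of 399 probes with a mean of at least 1 count per region, 21 passed, 10 that rose and 11 that fell, and 13 of them were probes of the genes above (edgeR quasi-likelihood test, Benjamini-Hochberg). Actg1 fell by 0.88 ± 0.26 on the log2 scale (SE; edgeR adjusted p = 0.0189), Smc3, a subunit of the cohesin ring, by 1.01 ± 0.31 (0.0233), and Nrgn, a calmodulin-binding protein, by 0.94 ± 0.30 (0.0335). Rnaset2a, a secreted ribonuclease, rose by 0.51 ± 0.15 (SE; edgeR adjusted p = 0.0122). The Itga2b probe stood at -0.76 ± 0.25 (SE; edgeR adjusted p = 0.0477), again for a gene whose protein chose the regions, and it left the threshold in 43 of the 83 fits that left out 1 region each. All of these genes but Itga2b fell outside the rule for named genes and were named after their values were seen.

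Of the 3 called probes without a gene name, each rested on 1 region. Probe RTS0071208 rose by 2.26 ± 0.58 (SE; edgeR adjusted p = 0.00676), with 77 counts in region 86 at 18 months and at most 3 elsewhere, and stood at -0.15 (edgeR adjusted p = 0.981) without that region. RTS0075031 rose by 1.60 ± 0.44 (edgeR adjusted p = 0.0122), with 34 counts in region 91 at 18 months, and stood at 0.82 (0.279) without it. RTS0069717 fell by 2.38 ± 0.68 (edgeR adjusted p = 0.017), with 75 counts in region 22 at 3 months, and stood at 0.18 (0.942) without it. Actg1 left the threshold without region 6 of the 3-month group (-0.81, edgeR adjusted p = 0.0533), Smc3 without region 24 or 41 (-0.94 and -0.85, adjusted p = 0.0527 and 0.0988), and Nrgn in 10 such fits, with an adjusted p of up to 0.0995. Across the alternatives Smc3 and Nrgn each did not pass in 8 of 16, Actg1 in 6 of 16 and Rnaset2a in 7 of 17. Without plate row A, chosen after seeing the data, Actg1 stood at -0.475, Smc3 at -0.88, Nrgn at -0.87 and Rnaset2a at 0.47 (edgeR adjusted p = 0.633, 0.132, 0.129 and 0.0675). Scaling by library size alone gave 35 probes, 9 that rose and 26 that fell. Here, too, the labels name no animals, and where some regions share an animal the p-values are too small.

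Measures of the regions themselves were compared by age with 2-sided permutation tests of 100000 resamples, adjusted over 5 measures. The mean log2 value of the 14 identity genes, Pf4 and Ppbp among them, was 0.65 ± 0.44 at 3 months and 0.38 ± 0.29 at 18 months (SD, n = 41 and 42), a difference of -0.27 (permutation p = 0.00119, adjusted p = 0.00298), with 30 of the 42 older regions below the 3-month median. Aligned reads per deduplicated count were 6.21 ± 0.85 at 3 months and 7.76 ± 1.03 at 18 months, a difference of 1.56 (permutation p = 1e-05, the smallest that these resamples can give, adjusted p = 5e-05), with 38 of the 42 older regions above the 3-month median. By plate row they averaged 5.11, 6.34, 6.64 and 6.56 in rows A to D and 7.44, 6.90, 8.06 and 8.665 in rows E to H. They thus also varied between rows of the same age, and age cannot be told from plate position here. Total counts (permutation p = 0.0771, adjusted p = 0.124), probes with a count (6628 ± 2014 and 7488 ± 2657, p = 0.101, adjusted p = 0.124) and the share of counts in the 50 most abundant probes (10.4 ± 0.85% and 10.8 ± 1.45%, p = 0.124, adjusted p = 0.124) were not past the threshold.

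The difference in the identity list was not alike in all regions. Among the lower-numbered regions of each age the list stood at 0.84 ± 0.48 and 0.32 ± 0.23 (SD, n = 21 and 21), a difference of -0.52 (permutation p = 6e-05, adjusted p = 0.0002). Among the higher-numbered regions it stood at 0.45 ± 0.28 and 0.45 ± 0.33 (SD, n = 20 and 21), a difference of -0.0013 (permutation p = 0.989, adjusted p = 0.989). These means carry no normalization and rise with the total count. Total counts averaged 9248.9 and 11166 at 3 and 18 months in the lower-numbered regions, and 9890.5 and 11881 in the higher-numbered ones. Both differences may therefore understate a lower list mean at 18 months. Within the 3-month regions Pf4 differed between these sets by -1.19 ± 0.22 on the log2 scale and Ppbp by -1.28 ± 0.27 (SE; edgeR adjusted p = 0.000133 and 0.00136), higher-numbered over lower-numbered. The age difference of the list differed between the sets by 0.52 ± 0.15 (SE; permutation p = 0.00058), a test chosen after seeing the data. The same question asked of each gene, with an edgeR interaction term also chosen after seeing the data, called 0 of 1233 genes, with 74 at an unadjusted p under 0.05 and the smallest adjusted p, 0.0529, at Pf4 (1.46). No other tool was run for that term. Without the regions of plate row A, the age difference of the identity list was -0.15 (permutation p = 0.0433, adjusted p = 0.108). Since no plate row held both ages, no difference could be given within a row. Regions that share an animal, which the labels leave open, make these p-values too small.

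The spread between regions, which for regions drawn around single megakaryocytes also takes in differences between cells, was compared by age over the 1233 genes. The median over genes of the SD of log2 values was 0.52 at 3 months and 0.59 at 18 months, a difference of 0.07. Of the 1233 genes, 910 had the higher SD at 18 months, against 706 on TMM-scaled log2 counts and 524 with counts thinned. A difference as large came from 14 of 100 splits of the regions into groups of the same sizes, the real split included. With every region thinned to 5000 counts, which left 36 and 41 regions, the medians were 0.28 and 0.26 and the difference was -0.02. No age difference in spread was detectable at this depth. In simulated counts of equal spread the difference in depth alone gave 0.09. The splits treat regions as independent, although some may share an animal, which the labels do not name.

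The last comparison asked whether regions with more megakaryocyte transcripts held fewer transcripts of other cells. The mean log2 value of the identity list was set against that of each of 6 lists of other marrow cells, within each age and pooled, which made 18 relations. The neutrophil, B cell, T and NK cell and bone lists had 1 measured gene each, and the neutrophil gene Padi4 lay close to background. Whether the counts of the listed genes came from other cells was not tested. With Benjamini-Hochberg adjustment, 7 relations were past the threshold by Pearson's r and 11 by Spearman's rho, all of them positive. The erythroid genes Hba-a1, Hbb-b1 and Hbb-b2 gave r = 0.43 (permutation p = 0.00428, adjusted p = 0.0161) and rho = 0.41 (permutation p = 0.00836, adjusted p = 0.0215) over the 41 regions at 3 months. Over the 42 regions at 18 months they gave r = 0.62 (permutation p = 8e-05, adjusted p = 0.00072) and rho = 0.45 (permutation p = 0.00345, adjusted p = 0.0197). Without the 2 regions farthest from the median of the identity list, r was 0.32 at 3 months (permutation p = 0.05) and 0.42 at 18 months (permutation p = 0.00801). Within the 8 plate rows r lay between -0.08 and 0.76, above 0 in 7. The bone marker Runx2 gave the lowest r, -0.07 at 18 months (permutation p = 0.675, adjusted p = 0.675).

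The deposited values carry no normalization, so a list mean rises with the total count of a region by construction, and the relations above share that dependence. For the identity list, Pf4 and Ppbp among its genes, the relation with the log2 total count had r = 0.58 and rho = 0.57 at 3 months (permutation p = 7e-05 and 0.00018, adjusted p = 7e-05 and 0.00028). At 18 months r was 0.63 and rho 0.54 (permutation p = 1e-05, the smallest these resamples can give, and 0.00028, adjusted p = 2e-05 and 0.00028). Without the 2 regions farthest from the median total count r was 0.54 and 0.50 (permutation p = 0.00023 and 0.00117), and within plate rows it lay between 0.49 and 0.94. With the linear trend on the log2 total count removed, 0 of the 18 relations with other cells were past the threshold by either coefficient, and the erythroid genes gave r = 0.11 at 3 months and 0.35 at 18 months (permutation p = 0.495 and 0.0243, adjusted p = 0.594 and 0.246). Regions of the same animal are not independent, and as the labels do not tie regions to animals these p-values are too small where some share an animal.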

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

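The edgeR gene count stayed between 10 and 20 under all 18 alternatives, against 14, and between 12 and 20 when each region was left out. Gm10265, Sprn, Marcks, 1110065P20Rik and Tmsb4x passed under all 18. Tysnd1 (1.24, adjusted p = 0.0663), Cd99 (0.65, 0.412) and Actb (-0.79, 0.101) did not pass with the lower-numbered regions alone, nor Ppbp (-0.68, 0.762), Cd9 (-0.80, 0.667) and Ppif (-0.25, 0.955) with the higher-numbered ones, and Tubb4b passed with neither (-1.46, 0.342, and -1.28, 0.496). Pf4 turned to 0.051 (adjusted p = 0.988) in the higher-numbered regions, and the cause was not tested. On log2 values with limma, Tubb4b, Ppif and Pf4 did not pass with a pseudocount of 0.5 (adjusted p = 0.431, 0.088 and 0.098) or 5 (0.417, 0.071 and 0.0523), after quantile normalization (0.586, 0.0665 and 0.12) or on the deposited table (0.426, 0.0793 and 0.0793), nor, with Cd9, in the Wilcoxon test. With edgeR on the deposited table Tubb4b had 0.997. The cause was not tested. With counts summed per plate row, Ppbp (-1.99, 0.297), Pf4 (-0.98, 0.488) and Gm52523 (1.05, 0.219) did not pass, with 8 units in place of 83. Under quantile normalization Chic2 (-0.46), Gm52800 (-0.49) and LOC118568632 (-0.40) were called lower, and Chic2 was with values rescaled to the same total (-0.25) or the all-probe total as library size (-0.26). Itga2b was called lower in 4 of 18 alternatives: rescaled values (-0.89, adjusted p = 0.0191), the all-probe total (-0.90, 0.0186), the deposited table (-0.74, 0.0342) and summed plate rows (-0.90, 0.0471). The edgeR probe count, 21 (10 up, 11 down), stayed between 19 and 23 when each region was left out. It was 35 (9 up, 26 down) with library size alone, 27 (9 up, 18 down) with the all-probe total, 13 with the higher-numbered regions, 13 without plate row A, 12 with thinned counts, 12 summed per plate row and 12 of 88 probes with a mean of at least 3. The last tests fewer probes and the subsets use fewer regions or counts. For the scalings, the cause was not tested. With no filter beyond 1 count in any region, edgeR did not call the probes of Actb (adjusted p = 0.132), Cd9 (0.145), Pf4 (0.18) and Ppif (0.252). Actg1 (0.4), Smc3 (0.336), Nrgn (0.438), Rnaset2a (0.298), RTS0069717 (0.18) and RTS0071208 (0.112) did not pass there either. Ppbp (2.24e-06), Tmsb4x (5.82e-06) and the genes that rose still passed. That setting adjusts over more probes. Among probes, DESeq2 left Actg1 (adjusted p = 0.0533), Smc3 (0.0969) and Nrgn (0.0969) not past the threshold, Actg1 stood at -0.41 (0.866) in the higher-numbered regions and had 0.182 summed per plate row, and Rnaset2a had 0.055 with library size alone, 0.087 with the all-probe total, 0.0654 with limma-voom and 0.0582 thinned. Probe RTS0069717 turned to 0.20 with DESeq2, 0.22 without shallow regions, 0.28 in the higher-numbered regions, 0.30 thinned and 0.18 with spikes removed. RTS0071208 turned to -0.10 with DESeq2, -0.85 in the lower-numbered regions and -0.19 with spikes removed. For both, 1 region held the counts. The 3 lists were called under 11 of 12 alternatives, and in the higher-numbered regions 1 was, the cytoskeleton list, while the identity (camera adjusted p = 0.879) and granule (0.845) lists were not, for which the cause was not tested. Of the region measures, 2 passed, and 1 passed in the higher-numbered regions and 1 without plate row A: the identity list then differed by -0.0013 and by -0.15, against -0.27, and the cause was not tested. Of the relations with other cells, 7 passed and 0 after removal of the depth trend, which the alternative removes by construction. The difference in spread was -0.017 thinned, 0.060 among the more abundant genes and 0.0085 on TMM-scaled log2 counts, none past the splits. No alternative fit exists for a few genes, such as Tubb4b among genes above the median mean. No paired analysis was possible because the region numbers of the ages do not overlap. Depth limits all of this, with a median table gene at 0.819 counts per region.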

Other observations

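Single regions at times held a high count of a transcript that was near absent elsewhere. Such counts, at least 20 in a region and at least 5 times the next region, were seen for 23 probes in 17 regions, 11 of the probes at 3 months and 12 at 18 months. Selplg, the P-selectin ligand of leukocytes, had 64 counts in region 19 at 3 months and at most 4 elsewhere. Vpreb1 had 63 in region 71, Plppr5, a phospholipid phosphatase-related membrane protein, 49 in region 89, and Ndufs6, a subunit of respiratory complex I, 34 in region 65, all at 18 months. Leprotl1, an endosomal membrane protein, had 28 in region 23 at 3 months. The other 18 probes had no gene name in the table.

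Regions 88 to 91, labelled 18 months and in plate row H, stood apart from the other 6 regions of that row, a set named after its values were seen. Gm10265 held 63.3 ± 13.0 counts per 10000 in them (SD, n = 4), 243 ± 52.9 in the other 6 and 60.9 ± 15.3 at 3 months (n = 41). Gm52523 held 35.6 ± 1.71, 77.7 ± 15.5 and 32.9 ± 11.9. Tmsb4x held 4.84 ± 1.24, 1.11 ± 0.97 and 6.46 ± 3.94, and Actb 6.34 ± 1.02, 3.00 ± 1.56 and 7.77 ± 3.35. Cd99 (3.42, 12.4 and 4.40), Sprn (1.91, 6.44 and 1.36), Marcks (5.05, 11.2 and 3.96), Tysnd1 (2.73, 5.91 and 1.21), Pf4 (8.73, 4.32 and 7.92), Cd9 (1.61, 0.658 and 2.06) and Tubb4b (0.792, 0.173 and 1.00) also lay nearer the 3-month mean. Ppif (1.04, 0.952 and 1.79) and Ppbp (2.49, 0.957 and 4.77) lay nearer the rest of the row, and 1110065P20Rik (5.26, 7.20 and 3.44) midway. Low values were also seen in row E, where Gm10265 held 83.4, 80.0, 89.2 and 93.8 in regions 48, 50, 51 and 53. Regions 88 to 91 are among the higher-numbered regions, and the comparisons of the higher-numbered regions were not repeated without them. The difference between regions 88 to 91 and the rest of the row was not tested.

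The tests of one shared loss of RNA, of plate rows, of neighbouring identifiers, of the depth of Cd9, Ppif and Tubb4b apart, of GC content by groups of genes, and those without regions 88 to 91 or without single genes were chosen after the result was seen. The edgeR gene test gave as many calls as the real ages in 1 of 100 splits of the regions, the real one itself, with at most 2 in any other. The probe test did so in 1 of 100, with at most 4 in any other, and the list test in 3 of 100, with at most 3. The spread difference was matched in 14 of 100, where another split reached 0.106. A split of independent regions by chance thus may explain the spread (14 of 100) but is an unlikely source of the gene calls (1 of 100). Other splits called as many lists as the real ages did, so list calls also arose without the real ages.

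For the lower Ppbp, Tmsb4x, Tubb4b, Cd9, Ppif, Actb and Pf4, with counts thinned to 5000, the median log2 fold change of the 6 genes with a tested probe was -0.98, against -1.16 in the same probe test unthinned, and Ppbp, Tmsb4x, Actb and Pf4 still passed, so depth does not explain those 4. The Cd9 probe went from -1.24 ± 0.28 to -0.73 ± 0.36 (SE; edgeR adjusted p = 0.372), the Ppif probe from -1.08 ± 0.29 to -1.10 ± 0.37 (0.0677) with a larger error from fewer counts, but with the log2 total count as a covariate 3 of 3 passed in the gene test, Cd9 (-1.27 ± 0.29), Ppif (-1.14 ± 0.29) and Tubb4b (-1.43 ± 0.365), which argues against depth as their whole cause. The risen genes held 1.08% of the counts at 3 months and 2.78% at 18 months, too small a share to explain the lower counts. Leaving them out of the total could hardly move a ratio, and 7 of 7 then had a 95% bootstrap interval below 0. Less megakaryocyte RNA stays open. The log2 ratios of 6 identity genes differed, from -2.40 for Ppbp to 0.35 for Rasgrp2 (heterogeneity p = 0.00316, and 0.00135 with plate rows resampled). A background of 0.422 counts per 10000 was subtracted first, so these ratios are not the fold changes given above. That heterogeneity test passed without Rasgrp2 (0.0417) but did not without Ppbp (0.0966) or without both (0.570). Plate rows with both ages numbered 0, so slide, animal or plate position cannot be told from age.

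For the higher Gm10265, Sprn, Tysnd1, Marcks, 1110065P20Rik, Gm52523 and Cd99, thinned counts gave a median log2 fold change of 1.07 with 7 of 7 probes still past the threshold, so depth does not explain them. After removal of a trend on transcript GC content the median of Sprn, Tysnd1, Marcks and 1110065P20Rik was 1.35 and the lowest 0.98, against a trend of at most 0.184. A trend on the GC content of whole transcripts thus does not explain these 4. For Gm10265, Gm52523 and Cd99, of which 0 had a GC value, it stays open. The GC content of the probe sequences, which the files do not give, was not examined and stays open for all 7. Between regions of the same age the 7 genes had a mean correlation of 0.469, above all 1000 sets matched on mean count (median 0.270, highest 0.467), and 0.437 without regions 88 to 91 (0.8% of sets as high), while the 7 genes that fell (0.220, 2.2% of sets as high) and the identity list (0.120, 0.9%) also went together. A factor shared by the risen probes that varies among regions of 1 age would give this, though such covariation is not particular to them. Whether such a factor gives the difference between the ages was not tested. Plate rows with both ages numbered 0 here too, so age cannot be told from slide, animal or plate position as the source of the difference between the ages.

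Whether the high counts in 1 region come from probes with neighbouring identifiers raised together stays open. Of the 23 probes, 6 pairs in the same region lay within 100 identifiers, but all 6 are pairs of the 4 probes in region 23, Leprotl1, RTS0070022, RTS0070056 and RTS0070078, which prompted the test. The other 19 probes had no such neighbour in their region.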
